A study of Arabidopsis thaliana with 4 samples.

How the data were processed

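Gene expression was measured in Arabidopsis thaliana seedlings labelled as the accession Landsberg erecta (Ler) on day 7, on 4 single-colour Cy3 NimbleGen arrays. Per the labels, 2 arrays held wild type and 2 held TEKi, plants carrying an artificial microRNA against TEK, and the replicates of a group came from separate cultures. TEK (AT2G42940) encodes an AT-hook DNA-binding protein.

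The authors deposited 1 intensity on a linear scale for each of 30361 gene models on each array. The method named in the submitters' processing notes is RMA, which corrects background, normalizes arrays to each other and summarises probes; its version and settings are not given in the sources used here. Each model rests on 1 to 3 probe pairs per the file headers (5 models on 1, 19073 on 2 and 11283 on 3), and every locus has 1 model. The highest intensity is 64046.8, which 342 to 419 genes reached on each array and 59 reached on all 4, so differences among the brightest genes are compressed. No detection flags were used, and a deposited error column was left out because its scale is not stated. Gene models and coordinates follow genome release 6, per the annotation column. Of these models, 100 stand for several loci that share their probes. Current symbols came from a RefSeq gene table of another assembly (TAIR10.1), used for names alone, in which 29976 of the 30361 loci matched. For arrays, their number limits the precision of each value.

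The same intensities were deposited in 2 forms, as a file per array and as a value table of the series. Each column of the value table was identical to exactly 1 array for all 30361 genes, but the columns of wild type 2 and TEKi 1 held the arrays filed as TEKi 1 and wild type 2. The array files were fixed as the source of the main result before the data were examined, with the value table as an alternative. Because the 2 sources put different arrays into each group, the complete set of comparisons was also made with the value-table labels, a step chosen after seeing the data. No array was relabelled by its values.

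Intensities were converted to log2 after 9 genes with an exact 0 on an array were left out, which left 30352 genes, and no pseudocount or filter on dim genes was applied. TEKi was compared with wild type by limma (lmFit and eBayes, 2-sided), with Benjamini-Hochberg adjustment over all genes and a threshold of adjusted p = 0.05. Any adjusted p for a gene is from that fit, and SE is the moderated standard error of the log2 difference, with n = 2 arrays in each group. Transposable element genes were those whose description in the deposited annotation names a transposon, transposase or retroelement (2449 of the genes tested). They were tested as a class by limma's camera with a preset correlation of 0.01, and by Fisher's exact test of their share among the genes called. The 19 gene lists were fixed from general knowledge before the data were examined, and the 18 with at least 5 measured members were tested by camera, adjusted over lists, with members also adjusted over the list alone. Those lists cover floral repressors, floral promoters, the autonomous pathway, RNA-directed DNA methylation, DNA methylation maintenance, loci silenced by DNA methylation, the AHL family, tapetum, floral organ identity, photosynthesis, root, seed maturation, salicylic acid defence, jasmonate, heat shock, cold and abscisic acid, the circadian clock and flavonoids. VIM2 and EVD, members of 2 lists, were not on the array.

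By the rule for named genes, TEK, FLC, FWA, FT and SOC1 were always named. The 10 largest rises and the 10 largest falls past the threshold with the arrays of the groups apart were candidates to be named, as were 5 transposable element genes in each direction and up to 4 members of each list. Where no gene passed, those with the smallest unadjusted p took their place. Genes named outside the rule were chosen after their values were seen. HSP101, AtGP1, AtMu1 and MULE, named below as list members, are among them.

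The alternatives were another quantile normalization, median centring, filters on dim genes, a pseudocount of 50, other variance models, a replicate block, a fold minimum of 2, a stricter adjusted p of 0.01, an estimated correlation in camera, the rotation test fry and leaving out each array. The alternative of averaging models of a locus changes nothing here, since no locus has more than 1, and was not run. Work was done in R 4.3.3 with limma 3.58.1.

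The procedure was tested on simulated data with the spread of the value-table groups and 30352 genes. With 200 changed genes, none of the 67 genes changed 4-fold and none of the 66 changed 16-fold reached adjusted p = 0.05, although 93.9% of the latter had an unadjusted p under it. With 1500 changed genes, 47.2% of those changed 4-fold and 83.4% of those changed 16-fold were recovered, with 54 false calls. A count of 0 in this design therefore does not show that genes were unchanged. Camera found 50 of 50 simulated lists shifted by 1 on the log2 scale and 0 of 50 unshifted ones. The simulated genes were independent and their lists random, so this does not show how often camera calls unshifted lists of correlated genes.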

Results

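Transcripts of 30352 genes were compared between seedlings of wild-type Ler and TEKi seedlings, in which an artificial microRNA is directed against TEK, an AT-hook DNA-binding protein. The labels give normal flowering time for wild type and late flowering for TEKi, and the series title names TEK as a silencer of transposable elements. Each group had 2 arrays from separate cultures, collected on day 7. Median intensity lay between 5639 and 5814 on the 4 arrays.

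The 2 deposited forms of the data did not assign the same arrays to the groups. Wild type 1 and TEKi 2 were the same array in both, whereas the array filed as wild type 2 stood under TEKi 1 in the value table and the array filed as TEKi 1 stood under wild type 2. The arrays resembled each other along the value-table labels. Across genes, which are not independent replicates, Pearson's r of log2 intensity was 0.972 between the 2 arrays that the value table labels wild type and 0.974 between the 2 that it labels TEKi. It was 0.934 between the 2 arrays filed as wild type and 0.930 between those filed as TEKi. Every comparison is therefore given first with the array-file labels, fixed as the main result, and then with the value-table labels, and groups are named by what the arrays are labelled in each source.

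The first question was the level of TEK itself, the target of the microRNA. TEK (AT2G42940, chromosome 2, 17869331 to 17870533, genome release 6) was bright on all 4 arrays and differed little between them. With the array-file labels its intensity was 13406 and 14118 in wild type and 9864 and 13770 in TEKi, a log2 difference of -0.24 (SE 0.249, n = 2 per group, adjusted p = 1). With the value-table labels it was 13406 and 9864 in the arrays labelled wild type and 14118 and 13770 in those labelled TEKi, a log2 difference of 0.28 (SE 0.226, n = 2 per group, adjusted p = 0.694). Neither difference exceeded the spread between replicates, so TEK did not settle which labels hold. Where the probes lie relative to the microRNA site is not given in the sources used here, and fragments left by cleavage can still bind a probe.

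Among the flowering genes named in advance, FWA and FLC had the widest range over the arrays. FWA, a homeobox gene that delays flowering when its DNA methylation is lost (chromosome 4, 13038369 to 13042452), had intensities of 39799 on wild type 1, 37534 on the array filed as TEKi 1, 350 on the array filed as wild type 2 and 111 on TEKi 2. FLC, a MADS-box repressor of flowering (chromosome 5, 3173498 to 3179449), had 30904, 15709, 767 and 314 on the same arrays in that order. With the array-file labels these high and low arrays fell into both groups, and the log2 difference was -0.87 for FWA (SE 4.22) and -1.13 for FLC (SE 3.03), each with adjusted p = 1 and n = 2 per group. With the value-table labels the deposited intensity of FWA was 196-fold lower in the arrays labelled TEKi (log2 difference -7.61, SE 0.642, n = 2 per group, adjusted p = 0.0357). That of FLC was 44.9-fold lower there (log2 difference -5.49, SE 0.629), which missed the threshold at adjusted p = 0.0624. SOC1, a promoter of flowering that FLC represses, had 9107 and 6778 in the arrays labelled wild type and 20772 and 23551 in those labelled TEKi (log2 difference 1.49, SE 0.232, adjusted p = 0.105). FT, the mobile flowering signal, stayed at or under 702 on every array and did not separate the groups under either set of labels (adjusted p = 1 and 0.873). The direction of FWA and FLC is the reverse of what the late-flowering label of TEKi and the silencing role in the series title would give. It was also the direction of the single pair of arrays whose labels do not differ between the sources, wild type 1 and TEKi 2.

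**Figure D1:**
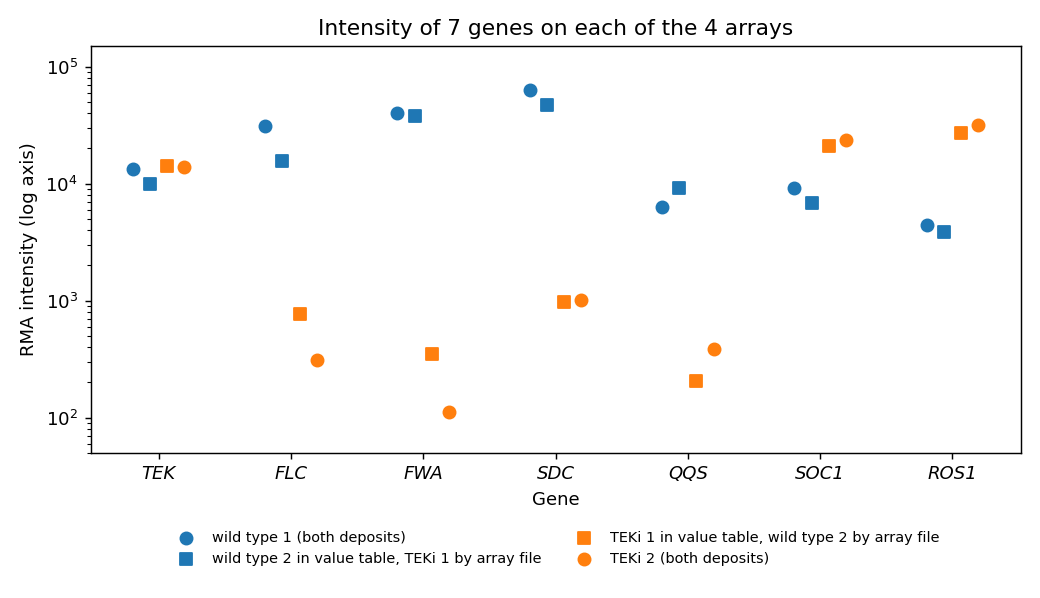
RMA intensity (vertical log axis) of 7 genes (horizontal axis) on the 4 arrays, 1 point per array, with colour for the value-table label and squares for the 2 arrays whose labels differ between the sources. FWA lies at 39799 and 37534 on the arrays labelled wild type in the value table and at 350 and 111 on those labelled TEKi, while TEK lies between 9864 and 14118 on all 4.

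With the array-file labels, no gene passed the threshold. The smallest unadjusted p values belonged to genes lower in TEKi, and among them Copia retrotransposons stood out in size. AT5G13205 had intensities of 12254 and 10212 in wild type and 82.3 and 59.8 in TEKi (log2 difference -7.32, SE 0.262, adjusted p = 0.805), and the Copia gene AT3G59720 had 14548 and 12087 against 289 and 227 (log2 difference -5.70, SE 0.235, adjusted p = 0.805). AT4G33720 had 14151 and 12923 in wild type and 623 and 677 in TEKi. On the other side, ELF4, a component of the circadian evening complex, had 4075 and 4202 in wild type and 13927 and 14978 in TEKi (log2 difference 1.80, SE 0.167, adjusted p = 1), and AT4G33980 had 1979 and 1713 against 8460 and 7883. These genes did not pass and are those with the smallest unadjusted p. Limma called 0 of 30352 genes (smallest adjusted p 0.805), 1398 genes had an unadjusted p under 0.05 (4.61%), and a test with plain per-gene variance also called 0, with 1373 genes under it.

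Gene lists with the array-file labels were led by heat shock and floral organ identity genes, whose measured members were mostly lower in TEKi. No single member passed over all genes. Of 11 heat shock genes, all had a negative log2 difference, with a median of -0.98, and 5 passed when adjusted over the list alone, among them the small heat shock protein gene HSP17.6A (2364 and 3901 in wild type, 548 and 631 in TEKi) and the chaperone gene HSP101 (31597 and 32563 against 17030 and 19529). All 10 floral organ identity genes also had a negative difference, with a median of -1.36, and 4 passed when adjusted over the list alone: SEP2 (2605 and 2129 against 684 and 462), STK, AG and SHP2. Camera with the preset correlation called both lists (adjusted p = 3.3e-09 and 4.72e-09), and with an estimated correlation each had adjusted p = 0.214. The estimate was 0.0103 for heat shock and -0.0782 for floral organ identity, against the preset 0.01. Higher correlation among their genes therefore does not account for the lost calls. Camera with the preset correlation also called the tapetum list towards TEKi-low (adjusted p = 0.0202, median -0.41, with the tapetal regulator AMS at 492 and 825 against 191 and 89.0). Root genes (adjusted p = 0.0202), cold and abscisic acid genes (adjusted p = 0.0363) and flavonoid genes (adjusted p = 0.0143) were called towards TEKi-high, with COR15B, a cold-regulated chloroplast protein gene, at 808 and 466 against 3015 and 2979. With an estimated correlation these 4 lists each had adjusted p = 0.763, and fry called 0 of the 18 lists. Without genes below the median level only the root and flavonoid lists were called, and lists left with fewer than 5 members were not tested.

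The other 12 lists did not pass with the array-file labels. In the circadian clock list (adjusted p = 0.449), 2 of 18 members passed when adjusted over the list alone, ELF4 and the blue-light receptor gene FKF1 (9737 and 6469 in wild type, 32763 and 31450 in TEKi). Among loci silenced by DNA methylation (adjusted p = 0.510), 1 of 9 did so, the heat-responsive Copia element ONSEN (AT1G11265, 12826 and 9194 against 84.4 and 187), whose model stands for 3 loci. No member passed over the list alone for jasmonate response (list adjusted p = 0.148), floral promoters (0.150), the AHL family (0.675), the autonomous pathway (0.873), RNA-directed DNA methylation (0.873), DNA methylation maintenance (0.873), salicylic acid defence (0.873), floral repressors (0.893), photosynthesis (0.953) or seed maturation (0.953). For floral repressors the camera direction was up while the median and the mean were below 0.

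With the value-table labels, 591 genes fell and 83 rose in the arrays labelled TEKi. No detection calls were used, so it is not known whether the dim values lie above background, and folds and ranks against them describe the deposited intensities, not transcript amounts. The largest fall in log2 intensity was that of the CACTA transposon gene AT5G45082 (chromosome 5, 18211526 to 18214078), with intensities of 52975 and 48340 in the arrays labelled wild type and 55.4 and 59.3 in those labelled TEKi (log2 difference -9.79, SE 0.164, n = 2 per group, adjusted p = 0.0128). CACTA genes AT5G32825, AT4G08091, AT4G03910 and AT1G42410 and Athila retroelement genes AT5G32306 and AT5G33050 were also among the 10 largest falls. The other 3 of the 10 largest falls lay outside transposons: AT1G66100 (43136 and 23382 against 42.2 and 52.1), annotated with toxin receptor binding, AT4G19500, annotated as a nucleotide-binding receptor (43665 and 38348 against 77.1 and 69.6), and DAR4 (21599 and 21944 against 82.5 and 33.6). The largest rise in log2 intensity was that of AT5G17090, of unknown function, from 81.4 and 97.3 in the arrays labelled wild type to 20861 and 14567 in those labelled TEKi (log2 difference 7.61, SE 0.266, adjusted p = 0.0128). AT5G17600, annotated as a ubiquitin ligase, rose 82.9-fold, and AT5G40060, a nucleotide-binding receptor gene, rose 38.4-fold. Of the 674 genes called, 87.7% fell, and each differed by over 2-fold, with 376 falls and 13 rises over 16-fold. The calls sat close to the threshold (smallest adjusted p 0.0128): 0 genes were called without any 1 of the 4 arrays (smallest adjusted p 0.0954 to 0.245), with a replicate block (0.0753), with plain per-gene variance (0.0975) or at adjusted p = 0.01. The count was 191 without the genes below the median level and 1150 with a mean-variance trend.

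Transposable element genes were the class the series title names. With the array-file labels none of them passed, and their median log2 difference was 0.013 against 0.0058 for other genes. Limma's camera did not call the class, and its direction was down although median and mean were above 0. The median was 0.29 without wild type 1 and 0.27 without TEKi 2, and -0.26 without wild type 2 and -0.30 without TEKi 1, each with a camera p past the threshold (0.0222, 0.0255, 0.00564 and 0.00934). With the value-table labels, 254 of 2449 transposable element genes fell and 8 rose in the arrays labelled TEKi. They made up 43.0% of the genes that fell against 8.07% of genes tested (odds ratio 9.46, 95% interval 7.96 to 11.2, Fisher's exact test, 2-sided p = 4.71e-121), and 9.64% of those that rose (odds ratio 1.22, exact p = 0.545). Genes are not independent replicates, so these Fisher's exact tests, and those below, do not measure spread between cultures. The median log2 difference of transposable element genes was -0.23 against 0.10 for other genes (camera p = 1.51e-11, 0.000933 with an estimated correlation). It was -1.34 without genes in the lowest quartile of level and -2.81 without those below the median level. Level is the mean over the arrays of both groups, so a gene dim in either group can stay by being bright in the other. The filter thus selects partly on the difference itself, and these larger medians do not show a stronger fall among well-measured genes.

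The fall was uneven over superfamilies. CACTA DNA transposons led it, with 112 of 340 genes fallen and a median log2 difference of -1.89. Of Athila retroelements 59 of 538 fell (median -0.33), of Mutator elements 28 of 278 (median -0.37) and of hAT elements 8 of 78 (median -0.20). Copia elements had 19 of 478 fallen and a median of 0.0043, other Gypsy elements 10 of 372 and LINE elements 11 of 299. Rises came from LINE gene AT5G23955, at 102 and 89.7 in the arrays labelled wild type and 3020 and 3193 in those labelled TEKi (32.5-fold, adjusted p = 0.0128), from the Copia gene AT1G21260 (10.6-fold), from LINE genes AT3G25815 and AT3G42890 and from the Gypsy gene AT4G32220 (8.48-fold), among others. Single calls were lost without any 1 array, while the camera p of the class was at most 4.53e-08 in those fits.

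**Figure D2:**
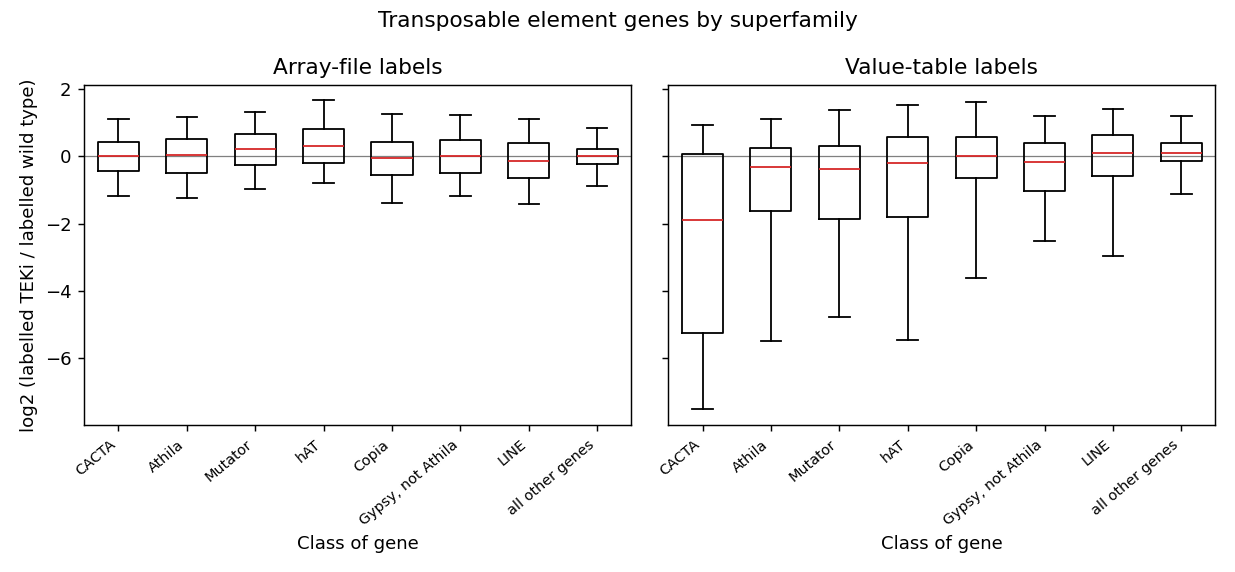
Log2 difference between the arrays labelled TEKi and those labelled wild type (vertical axis) for 7 transposable element superfamilies and for genes outside the class (horizontal axis), with the array-file labels on the left and the value-table labels on the right. Boxes span the quartiles with the median in red and whiskers run from the 5th to the 95th percentile of genes; the CACTA median is -1.89 on the right.

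Among the lists with the value-table labels, loci silenced by DNA methylation passed (camera adjusted p = 0.0154, median -3.14), but not with an estimated correlation (adjusted p = 0.806). That estimate was -0.0499, below the preset, so higher correlation does not account for the lost call. With the replicate block, without wild type 1, without genes below the median level and by fry (adjusted p = 0.0863), 0 lists passed. Of its 9 measured members 4 fell in the arrays labelled TEKi. IS112A (AT4G04293) had 32631 and 31560 in the arrays labelled wild type and 116 and 130 in those labelled TEKi (261-fold, adjusted p = 0.0128). SDC, an F-box gene kept silent by methylation, fell 54.4-fold (adjusted p = 0.0133), and QQS, a starch regulator with epigenetically variable expression, fell 27.1-fold (adjusted p = 0.0410), beside FWA. AtGP1 was lower as well (log2 difference -3.14) and AtMu1 (log2 difference 0.66) and MULE (1.52) lay on the other side. MULE was dim on every array, at 42.4 and 26.9 in the arrays labelled wild type and 114 and 82.0 in those labelled TEKi. AtGP1, AtMu1 and MULE passed only when adjusted over the list alone, which gave 5 members lower and 2 higher.

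ROS1, the 5-methylcytosine DNA glycosylase that removes methylation, had 4387 and 3879 in the arrays labelled wild type and 26846 and 31391 in those labelled TEKi, a rise of 7.04-fold (log2 difference 2.81, SE 0.186, adjusted p = 0.0246), the 1 call among 18 measured maintenance and heterochromatin genes (list adjusted p = 0.649). In RNA-directed DNA methylation (list adjusted p = 0.392) none of 18 passed over all genes, and NRPE1, the largest subunit of RNA polymerase V, passed over the list alone (6736 and 6840 against 22325 and 28660, adjusted p over all genes 0.0551). Of 17 floral repressors (list adjusted p = 0.270) FWA fell, and FWA, FLC and MAF4 passed over the list alone, with MAF4 at 1356 and 1671 against 436 and 490. Of 16 seed maturation genes (list adjusted p = 0.211) the storage protein gene CRA1 fell 14.9-fold (15671 and 14517 against 739 and 1388, adjusted p = 0.0464).

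In the other 13 lists no member passed over all genes with the value-table labels. In the tapetum list (adjusted p = 0.270) the pollen wall gene LAP6 passed over the list alone, at 2701 and 2966 against 14025 and 9940, and in the heat shock list (0.683) HSP22.0 did, at 101 and 96.9 against 2767 and 972. List adjusted p was 0.158 for flavonoids, 0.238 for root, salicylic acid defence and cold and abscisic acid, 0.270 for the AHL family, 0.466 for the autonomous pathway, 0.535 for jasmonate response, 0.683 for floral promoters and photosynthesis, 0.751 for floral organ identity and 0.931 for the circadian clock. For floral organ identity and floral promoters the median was below 0 and the mean above it, and for floral repressors the median was above 0 and the mean below it.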

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

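The alternatives for the value-table labels, and the one without genes at the highest value, were chosen after seeing the data; the others were fixed before. With the array-file labels 0 genes were called under every setting except the value-table labels (674). TEK (-0.24) became 0.28 with the value-table labels and ran from -0.48 to 0.0014 without single arrays. The transposable element median (0.013) became -0.23 with the value-table labels, -0.022 after median centring and -0.10 without genes below the median level, and ran from -0.30 to 0.29 without single arrays. The number of lists called, 6, became 1 with the value-table labels (loci silenced by DNA methylation, not among the 6), 2 without those genes, 0 with an estimated correlation, 0 with fry and 2 to 7 without single arrays, where lists outside the 6 also passed. With the value-table labels, the 674 genes became 0 by the array-file labels, 191 without those genes, 1150 with a mean-variance trend, 0 with the replicate block, 0 with plain variance, 0 at adjusted p = 0.01 and 0 to 0 without single arrays, where fewer samples leave fewer degrees of freedom. Other settings gave 577 to 906 genes, of which the quantile fit shared 653. TEK (0.28) ran from 0.057 without wild type 2 to 0.50 without wild type 1. It became -0.24 and the transposable element median (-0.23) 0.013 by the array-file labels. The transposable element class kept its direction and camera p under 0.05 in the other fits. Filters on level, a mean over the arrays of both groups, select partly on the difference itself. With them the median of the class moved to -1.34 without genes in the lowest quartile of level and to -2.81 without those below the median level. The 1 list called became 6 by the array-file labels, and 0 without those genes, with the replicate block, with an estimated correlation and with fry, and 0 to 5 without single arrays. Of the named genes called with the value-table labels, 10 had the other sign by the array-file labels, where none was called: AT5G17090 -0.13, AT5G23955 -0.051, AT2G05185 -0.46, AT5G32825 0.45, AT1G42410 0.32, AT1G21260 -0.41, AT3G25815 -0.24, IS112A 0.058, QQS 0.74 and CRA1 0.40. Of the alternatives for named genes with the value-table labels, 1048 left the call as it was, 173 ended it, 14 made one and 32 changed the sign of a value that was not called. With the array-file labels those counts were 1267, 0, 1 and 55. Same-numbered arrays deviated together with r = 0.65 under the array-file labels and 0.11 under the value-table labels; with 2 pairs this shows a shared number, not a pairing, and the replicate block left 0 calls with the array-file labels. Beyond what a setting itself changes (the arrays in a group, the number of samples), the cause of each change was not tested. No detection flags were used, so signal over background does not limit these counts in a known way.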

Other observations

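All tests in this part were chosen after the results were seen, except the count of genes next to a transposable element gene, whose outcomes were written down before it was run; its version within windows and that of fallen neighbours came after. Among the genes with the smallest unadjusted p under the array-file labels, the Copia genes share an identity. AT1G11265 is a copy of ONSEN, a retrotransposon activated by heat, and 24 measured Copia genes have the same best protein match in the deposited annotation. Of these, 6 were over 16-fold lower in the arrays filed as TEKi than in those filed as wild type (AT5G13205, AT1G11265, AT3G61330, AT3G59720, AT1G48710 and AT3G32415). Their intensities were 8816 to 14548 in the 2 arrays filed as wild type and 59.8 to 305 in the 2 filed as TEKi, though the smallest adjusted p was 0.805. The other genes with this match changed less, and AT3G30815 and AT3G43352 were higher in both arrays filed as TEKi. These last were dim on every array: AT3G30815 had 75.5 and 87.1 in the arrays filed as wild type and 210 and 277 in those filed as TEKi. AT3G43352 had 38.8 and 55.7 against 137 and 86.5. All 11 heat shock genes had a negative log2 difference, as these 6 did. Of the 11, 5 passed over the list alone and 0 over all genes, and camera with an estimated correlation did not call the list (adjusted p = 0.214). Copies of ONSEN can cross-hybridise, so 6 genes need not mean 6 active copies. The value table gives these 2 brighter arrays replicate number 1 in each of its groups.

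With the value-table labels, 337 genes outside the transposable element class fell and 75 rose. Pseudogenes made up 31.2% of the former against 4.0% of other genes (odds ratio 10.9, adjusted p = 2.18e-59 over 24 Fisher's exact tests). They were 3 of the 75 that rose, and falls were not tested against rises. Genes described as unknown or hypothetical made up 76.0% of the falls against 43.4%. Protein kinases (2 genes, odds ratio 0.115, adjusted p = 8.37e-05) and transcription factors (3 genes, odds ratio 0.145, adjusted p = 3.27e-05) were rarer among the falls than among other genes. AOP2 and AOP3, neighbouring glucosinolate biosynthesis genes chosen after their values were seen, went opposite ways. AOP2 had 62598 and 62123 in the arrays labelled wild type and 1244 and 209 in those labelled TEKi (adjusted p = 0.0903), and AOP3 had 502 and 2508 against 25323 and 25696 (adjusted p = 0.159). Expression of both is known to vary between accessions, and whether the plants on all 4 arrays shared the labelled Ler background was not tested with these genes.

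For the first pattern, the conflict between the deposits over wild type 2 and TEKi 1, a candidate explanation is that the 2 array files are exchanged: each of these arrays correlated better with the undisputed array of its value-table group than with that of its array-file group, by at least 0.040. A batch, named in no label, that follows the replicate number of the array files and outweighs genotype cannot be told apart from it, since both give same-numbered arrays that deviate together (r = 0.65). For this batch the fit with the replicate block was to call genes, and it called 0. That does not decide, since a small genotype effect also gives 0 calls and the fit leaves few residual degrees of freedom. The value-table labels gave 674 calls and the highest of the other 2 splits of the arrays into pairs gave 0, but 3 splits are too few for a share under 0.05. The 4 arrays were on 1 slide, and position on it was not tested.

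For the second pattern, FWA and transposable element genes higher in the arrays the value table labels wild type, a single scale factor per array is argued against, since it would move all genes alike: as deposited, the transposable element median minus that of other genes was -0.33 on the log2 scale. That test was chosen with its value already known, in place of the same difference after quantile normalization, which hardly moved it, and after median centring, which cannot move it. A difference between arrays that depends on mean level is argued against as the whole cause. Removing the trend of other genes over 50 bins of level from each array moved genes by a median of 0.14. The transposable element median minus that of other genes was then -0.42, and camera called the class with the preset and an estimated correlation. Level is the mean over the arrays of both groups. A gene bright in either group and dim in the other was thus matched to genes of intermediate level. A dependence on the intensity of a gene on each single array was therefore not tested. Probe sets that stand for several loci covered 3 of the 254 transposable element genes that fell (1.18%) and 21 of the 2449 tested. With so few on the array, exact sharing could not have accounted for most of the falls, whatever the outcome. Partial cross-hybridisation was not tested. An exchange of the group names in the value table could give the direction and stays open, since TEK, higher in the arrays labelled TEKi by 0.28 (log2) with limma's adjusted p = 0.694, decides nothing; sequence or background differences between the plants were not tested on these genes and stay open too.

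The third pattern is the set of 337 genes outside the transposable element class. A neighbouring transposable element gene may be part of the explanation: 54.3% of them had one next to them against 8.26% of other genes (odds ratio 13.2, 95% interval 10.5 to 16.5), and 16% of the genes that rose did. Within windows of 1 Mb, which allow for position near centromeres, the odds ratio was 2.76 (2.06 to 3.69). The neighbour had itself fallen for 22.4% of the 183 fallen genes next to one, against 9.61% of the 2278 others next to one (odds ratio 2.71). That second comparison was made without windows and does not allow for position. Some pseudogenes and unknown genes could themselves be unannotated transposon copies. Sequence differences between the plants of the groups, as between accessions, also stay open. Genes described as nucleotide-binding receptors, which vary in sequence, were over-represented among the falls (5 genes, odds ratio 4.22, Fisher's exact test, adjusted p = 0.0333). Of the rises, 1 gene had such a description (odds ratio 3.67), with an interval too wide to tell (0.0909 to 21.6). The class was taken from descriptions and can miss members, so the count of rises does not argue against sequence differences.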
